A study of Oryza sativa with 96 samples.

How the data were processed

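Leaf RNA of rice (Oryza sativa, variety Koshihikari) from a paddy field at Tsukuba was measured in 96 samples of 2013 on 48 Agilent 2-colour arrays. Each array carried a different leaf sample in the Cy3 and in the Cy5 channel. The arrays lay on 12 slides and were scanned on 2 days, the earlier for samples of June 5 to July 1 and the later for samples of July 2 to July 16. Per the labels' protocols, total RNA was extracted on a Maxwell instrument and labelled by a low-input amplification kit.

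Per the file headers, Agilent Feature Extraction 10.5.1.1 (protocol GE2_105_Dec08) turned the scans into spot intensities: a mean signal intensity, a local background intensity and a processed signal intensity that is background-subtracted and dye-normalized within the array. The authors also deposited a table of log2 values for 125722 probes, made with affy per the submitters' processing notes. The values themselves show 1 common distribution over all 96 columns (medians of 5.70 to 5.71 log2). Their ranks followed the processed signal of the sample's own channel in 96 of 96 samples (lowest rank correlation 1.00, against at most 0.987 for the other channel of the array).

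The comparisons here started from the mean signal and the local background. Background was corrected by limma's normexp method with an offset of 50, the channels of each array were aligned by a loess curve, and average intensities were quantile-normalized between arrays, all in limma 3.58.1 under R 4.3.3. Values are log2 intensities of single channels. Spots marked as outliers by the scanner software (3 to 233 per sample, median 46.5) were set to missing. Of 151878 probes, 101440 were well above background in at least 10 samples and were tested. Per sample, 51.2% to 63.4% of probes were well above background, and no spot was saturated. The number of arrays, not a read depth, limits the precision.

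No probe carries a gene name or description in the files used here, the header's build (IRGSP5:v5:Jun2008) comes without probe positions, and 0 probe IDs occur in the reference gene table. Gene lists fixed beforehand, for nitrogen, phosphate, photosynthesis, clock, stress and tissue marker genes, therefore had 0 matched members and were not tested. Results are counts of probes, and several probes can read 1 transcript: joined by shared runs of 25 bases, the tested probes form 65119 sequence sets, of which 41778 hold 1 probe.

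The rule for naming genes asked for a symbol or description, so by that rule 0 probes would be named. The probes named here are an exception made after their values were seen. They are, for each comparison, at most 2 that rose and 2 that fell most among those with adjusted p under 0.05, the same direction at 80% or more of the sampling times (dates for the time of day), and a signal well above background in 50% or more of the samples of 1 of the compared sets. For the slope on days, the direction clause does not apply. A few further values of these named probes in other comparisons are given with the adjusted p.

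Transplanting dates, sampling times and labels define the groups. Each sampling time has 1 sample per transplanting date and label, so the sampling times are the replicates. The label effects came from 1 linear model of all 96 samples with each sampling time and transplanting date as a replicate block (32 blocks), a dye term, and the array as a random block (consensus correlation 0.24). A second model split the label effects by days after fertilization (correlation 0.20). Moderated statistics followed limma, two-sided, with Benjamini-Hochberg adjustment over all fitted probes and a threshold of 0.05. The time of day was tested on the 16:20 minus 10:40 differences of 6 dates. The transplanting date was tested within 11 sampling times of unfertilized plants, and the slope on days in 21 unfertilized early samples with terms for time of day and dye. In the transplanting model the array is nested in the sampling time at most times, and its estimated correlation of -0.81 has no meaning as a shared error. The count without the array block stands beside that result.

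The transfer of an effect from the probes called in 1 comparison to another comparison was tested by an exact two-sided permutation test. For the slope on days, the transplanting date and late plants before July 2, the scored times also held samples that chose the probes. These lay in part on the scored arrays. The score of a sampling time gives equal weight to the probes called higher and to those called lower in another comparison. It is the average of the mean change of the higher probes and the mean change, sign turned, of the lower ones. All sign flips of the sampling times were enumerated. The 12 such tests form 1 family for the Benjamini-Hochberg adjustment. They were chosen after the results of the linear models were seen, and so were leaving out each sampling time in turn from them and taking 1 mean score per date. With a time left out, the adjustment exchanged that 1 test among the 12 and did not count the other times tried. The 8 times after July 2 fall on 6 dates, and times of 1 date may not be independent.

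The linear models were tested on simulated data, in which 100 probes were changed by 0.5 log2 and 100 by 1 log2 among 99015. After the first fertilization 90% and 99% of these were recovered with 7 false calls, after the second in early plants 84% and 99%, and after the second in late plants 78% and 98%. Before any fertilization, 43% and 87% were recovered. For the slope on days, 46% and 90% were recovered. The simulated probes varied independently of each other, which real probes need not do, so the false calls of the real data can be more. With labels reshuffled among the real samples, up to 4901 probes were called for the first fertilization in early plants.

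The alternatives were the processed signal, no loess, the authors' table, other filters on dim probes, no array block, no dye term, a slide block, no replicate block, 1 mean per date, a 2-fold threshold, other sample sets, and each sampling time left out in turn. The comparisons by linear models and these alternatives were chosen before the data were examined. The alternatives without June 7 and without the array of both July 11 Fer2 samples were added after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.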

Results

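Leaves of field-grown Koshihikari rice were profiled in 96 samples, taken from June 5 to July 16 of 2013 at 10:40 (10:50 on June 5) or 16:20. The series text gives 16:40 for the afternoon. Seedlings had been transplanted on May 28 (early) or June 11 (late). Plants carried 1 of 3 labels: none, Fer1 (fertilizer at 9:00 on June 6) or Fer2 (fertilizer on June 6 and again at 9:00 on July 2). The fertilizer is not named. The labels add that part of the Fer1 and Fer2 plants received no fertilizer, without saying which, and do not say what late plants received for the date of June 6, which precedes their transplanting.

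Early plants were sampled at 2 times before any fertilization, at 11 times between the dates of fertilization and at 8 times after July 2. Late plants were sampled at 3 times before and 8 times after July 2. Each time has 1 sample per label and no replicate, so the sampling times stand in for replicates. The p-values below therefore weigh a difference against its variation over times or dates, not between separately treated plots or plants. Each n below counts samples, which can include several labels or both transplantings of the same time. In each sample, 51.2% to 63.4% of 151878 probes stood well above background, and 101440 probes were tested. The median spot intensity was 84.1 in Cy3 and 153 in Cy5 samples. Probes have no gene names in the files used here. They are named by their IDs and 60-base sequences, and were chosen after their values were seen.

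Samples differed most by time of day and by calendar date. The first principal component held 55.0% of the variance, and the time of day accounted for 94.2% of it. The second held 12.1%, of which the sampling day accounted for 81.2% and the slide for 86.6%. Each slide held samples of few dates, so date and slide are not separated there. The labels accounted for 0.0276% and 0.507% of these components.

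**Figure D1:**
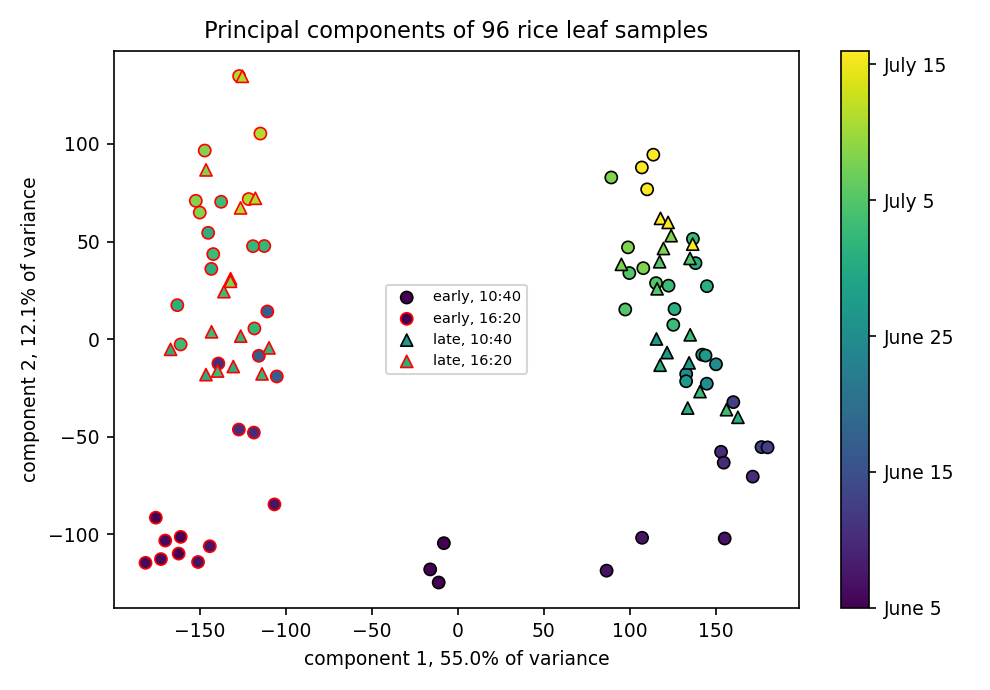
Each point is 1 of 96 samples, placed by its scores on component 1 (55.0% of variance) and component 2 (12.1%), with the color giving the sampling date, circles for early and triangles for late transplanting, and black or red outlines for 10:40 or 16:20. Morning and afternoon samples separate along component 1, except that the 3 samples of June 5 at 10:50 lie between them, and dates follow component 2.

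Did the fertilization of June 6 change the leaves of early plants? Fertilized leaves (Fer1 and Fer2) differed from unfertilized ones in 7222 of 101437 probes, 2446 higher and 4776 lower. The changes were small, with a median size of 0.19 log2, and 39 probes changed at least 2-fold (22 higher, 17 lower). The called probes fall into 5104 sequence sets, and 2 of these hold calls of both directions. Probe eAry2_31212 (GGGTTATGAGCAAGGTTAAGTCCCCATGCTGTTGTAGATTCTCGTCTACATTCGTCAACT) was lower in fertilized leaves at 11 of 11 sampling times. Its signal was 12.80 ± 1.12 log2 (SD, n = 22) with and 14.53 ± 0.84 (n = 11) without fertilizer, and the fitted change was -1.80 ± 0.30 (SE, limma adjusted p = 9.08e-05). Probe eAry1_36698, which shares a run of 30 bases with it, fell by 1.77 on the log2 scale at the same 11 times (adjusted p = 8.45e-05). Probe eAry2_30365 (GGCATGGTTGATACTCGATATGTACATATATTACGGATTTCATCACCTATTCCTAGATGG) was higher at 9 of 11 times, by 2.33 ± 0.42 log2 (adjusted p = 0.000280). The overlapping probe 44kb3_35804 rose by 2.26 log2 (adjusted p = 0.000171). With a slide block the count was 5157, and all these samples were scanned on 1 day. It was 4271 without a dye term, 3087 without the replicate block and 3397 with 1 mean per date, and 3662, 4447 and 4796 without June 10 at 16:20, June 17 and June 25.

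The response was traced by days after June 6. On days 0 to 1, 6088 probes differed (3530 higher, 2558 lower), a count that 13 of 100 splits of the labels reached, on days 4 to 11 5644 (2389 and 3255), and on days 19 to 25 limma called 0 probes, with 4832 at an unadjusted p under 0.05, where chance gives 5072 of 101437. For eAry2_31212 the change was -1.63 ± 0.51 log2 (adjusted p = 0.0444) on days 0 to 1 and -2.63 ± 0.45 (adjusted p = 0.000366) on days 4 to 11. On days 19 to 25 it was -0.99 ± 0.47 (adjusted p = 1.00). For eAry2_30365 the difference was 4.40 ± 0.74 log2 (adjusted p = 0.00130) on days 0 to 1. It came with a fall in unfertilized leaves, which stood at 12.47 and 13.49 log2 on June 5 and between 6.65 and 7.55 on June 6 and 7. Leaves labelled Fer1 or Fer2 stood at 10.75 or more on June 5 and between 7.41 and 14.25 on June 6 and 7, and at 10:40 on June 7 Fer1 (7.41) was not above the unfertilized label (7.55). The values on days 4 to 11 and 19 to 25 were 0.73 ± 0.65 (adjusted p = 0.562) and 2.33 ± 0.68 (adjusted p = 0.716). The first-stage count was 171 without June 7 at 16:20, 118 without both June 7 times, which leaves 1 time, and 3232 without a dye term. The middle-stage count was 3603 and 2084 without June 10 at 10:40 and 16:20, 2156 without June 17, 3737 in the authors' table, 2858 without a dye term and 2653 with a slide block.

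Sets that differ in label but not in treatment show the background of such counts. Between June 6 and July 1, Fer2 and Fer1 plants had the same history by the dates in the labels, and limma called 0 probes between them, with 7890 at an unadjusted p under 0.05. Leaving out June 13, June 25 or June 27 gave 16, 5 and 2, and leaving out July 1 at 16:20, when Fer2 leaves resembled those after July 2 in eAry2_31212, gave 0 (6480 at an unadjusted p under 0.05). On June 5, before any fertilization, 89 probes already differed between the labels (33 higher, 56 lower in Fer1 and Fer2), in only 2 sampling times, although 2337 had an unadjusted p under 0.05, where chance gives 5072. Among them 44kb3_43477 was higher by 1.51 ± 0.25 log2 (adjusted p = 0.000691) and eAry2_07376 by 1.46 ± 0.32 (adjusted p = 0.0375), and neither was called with the processed signal (2.01 and 1.92, both adjusted p = 1.00). Over 11 alternatives 44kb3_43477 lost its call in 3 and eAry2_07376 in 8. Lower were eAry1_26111, by -1.80 ± 0.17 log2 (adjusted p = 1.68e-09), and eAry1_31460, by -1.60 ± 0.25 (adjusted p = 0.000222), each at 2 of 2 times. They were well above background in 3 of 4 and 2 of 4 samples of Fer1 and Fer2 and in 2 of 2 and 1 of 2 of the unfertilized label, so these sizes depend on how dim signal is treated: with the processed signal eAry1_26111 stayed called, at -3.05, and eAry1_31460 did not, at -2.83 (adjusted p = 0.407), and in the authors' table eAry1_26111 had -0.99 (adjusted p = 1.00). In both, the unfertilized label varied by a larger SD (1.84 and 2.05 log2, n = 2) than Fer1 and Fer2 (0.47 and 0.03, n = 4). The June 5 count was 480 without the morning and 185 without the afternoon, 22 with the processed signal, 54 without loess, 18 in the authors' table, and 510 or 26 with no filter or the stricter filter on dim probes.

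In late plants before July 2, the labels differed in 12 probes, all lower in Fer1 and Fer2, a count that 5 of 27 splits of the labels reached (3019 at an unadjusted p under 0.05). Probe eAry2_22024 was lower by -1.33 ± 0.24 log2 (adjusted p = 0.0287) and 44kb3_44548 by -1.19 ± 0.23 (adjusted p = 0.0350), each at 3 of 3 times. Either probe was well above background in 2 of 6 samples of Fer1 and Fer2 and in 2 of 3 of the unfertilized label. The size of the change therefore depends on how dim signal is treated: with the processed signal it was -2.79 (adjusted p = 0.205) and -2.52 (adjusted p = 0.484). Both calls rest on June 27: without it the values were -0.22 (adjusted p = 0.981) and -0.18 (adjusted p = 0.981), and the count was 3, while it was 73 and 84 without July 1 at 10:40 or 16:20. The count was 0 with the processed signal, in the authors' table and with a slide block (3195, 2690 and 2666 at an unadjusted p under 0.05), 2 without the replicate block, 20 without loess or without the array block, 56 with 1 mean per date, and 151 with no filter on dim probes.

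Did the fertilization of July 2 change the leaves? Fer2 was compared with Fer1 at 8 sampling times. By the dates in the labels they differ in that treatment alone, but the labels do not say which of these plants received no fertilizer. In early plants 5456 probes differed, 1882 higher and 3574 lower in Fer2, of which 144 differed at least 2-fold (71 higher, 73 lower). Probe eAry2_31212 fell again, at 8 of 8 times, from 14.30 ± 0.69 log2 (SD, n = 8) in Fer1 to 11.70 ± 2.18 (n = 8) in Fer2, a fitted change of -2.64 ± 0.42 (SE, limma adjusted p = 4.22e-05). Its partner eAry1_36698 fell by 2.65 on the log2 scale (adjusted p = 2.76e-05). Probe 44kb3_26886 (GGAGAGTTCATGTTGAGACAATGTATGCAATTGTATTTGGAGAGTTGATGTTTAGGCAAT) was higher at 8 of 8 times, at 10.17 ± 1.59 log2 in Fer2 and 7.86 ± 0.77 in Fer1, a change of 2.35 ± 0.33 (adjusted p = 5.25e-06). The overlapping maskBest_02949 rose by 2.28 log2 (adjusted p = 4.08e-06). The same 44kb3_26886 had risen by 1.26 ± 0.23 log2 (adjusted p = 0.000326) after June 6. The count was 3654 with a slide block, and all these samples were scanned on 1 day. It was 184 without the replicate block, 2524 with 1 mean per date, 8549 without the array of both July 11 Fer2 samples, 3009 and 2394 without July 3 at 10:40 and 16:20, 3504 without July 5 and 3545 without July 8 at 16:20.

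In late plants 969 probes differed at the same 8 times, 322 higher and 647 lower in Fer2, and 66 of them at least 2-fold (24 higher, 42 lower). Probe eAry2_31212 fell from 13.57 ± 1.13 log2 (SD, n = 8) in Fer1 to 10.97 ± 2.02 (n = 8) in Fer2, by a fitted -2.63 ± 0.42 (SE, limma adjusted p = 0.000202), and eAry1_36698 fell by 2.66 on the log2 scale (adjusted p = 0.000131). Probe 44kb3_26886 rose by 1.78 ± 0.33 log2 (adjusted p = 0.00156), from 9.05 ± 1.25 to 10.84 ± 1.28. Probe eAry2_08362 (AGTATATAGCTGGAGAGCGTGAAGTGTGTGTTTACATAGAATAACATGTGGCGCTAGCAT) rose by 1.75 ± 0.36 log2 (adjusted p = 0.00553), each at 8 of 8 times. Late Fer2 stood below late Fer1 in eAry2_31212 before July 2 as well: 13.25 against 13.59 log2 on June 27. On July 1 it was 12.07 against 13.05 at 10:40 and 9.97 against 11.79 at 16:20. For 44kb3_26886, late Fer2 was above Fer1 on June 27 (11.04 against 10.46) and on July 1 at 16:20 (11.60 against 10.76). It was not at 10:40 (11.13 against 11.26). The late changes beyond these earlier gaps were not tested. The count was 724 with a slide block, 195 with 1 mean per date and 0 without the replicate block (2380 at an unadjusted p under 0.05), where eAry2_31212 and eAry1_36698 (both adjusted p = 0.120), 44kb3_26886 (0.151) and eAry2_08362 (1.00) lost their calls. With 1 mean per date 44kb3_26886 (adjusted p = 0.0632) and eAry2_08362 (0.0844) lost theirs; without July 3 at 16:20 or July 5 the count was 625 and 545, and without July 8 at 10:40 or 16:20 it was 219 and 215, with eAry2_08362 at adjusted p = 0.0662 and 0.0602.

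A difference in response between late and early plants was tested directly. For late minus early, limma called 0 probes, with 1439 at an unadjusted p under 0.05, fewer than the 5072 that chance gives. For eAry2_31212 that difference was 0.02 ± 0.54 log2 (adjusted p = 1.00) and for 44kb3_26886 it was -0.56 ± 0.42 (adjusted p = 1.00). Across probes the 2 sets of changes had r = 0.79, where probes are not independent replicates and the early and late Fer2 samples share an array at 8 of 8 times. A second direct test took the Fer2 minus Fer1 difference after July 2 beyond that between June 6 and July 1. In early plants 340 probes differed (100 higher, 240 lower), among them eAry2_31212 (-2.36 ± 0.54 log2, adjusted p = 0.0320) and 44kb3_26886 (1.88 ± 0.42, adjusted p = 0.0278). That count was 0 without the replicate block (6515 at an unadjusted p under 0.05), 14 with 1 mean per date, 23 with a slide block, 142 without a dye term, 154 without the array block, 163 with the processed signal, 216 in the authors' table and 213 with no filter on dim probes. Leaving out 1 sampling time moved it as well: to 133 (June 6), 221 (June 7 at 10:40), 139 (June 25), 111 and 622 (July 1 at 10:40 and 16:20), 53 and 59 (July 3 at 10:40 and 16:20), 142 (July 5), 139 and 131 (July 8 at 10:40 and 16:20) and 680 (July 16).

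**Figure D2:**
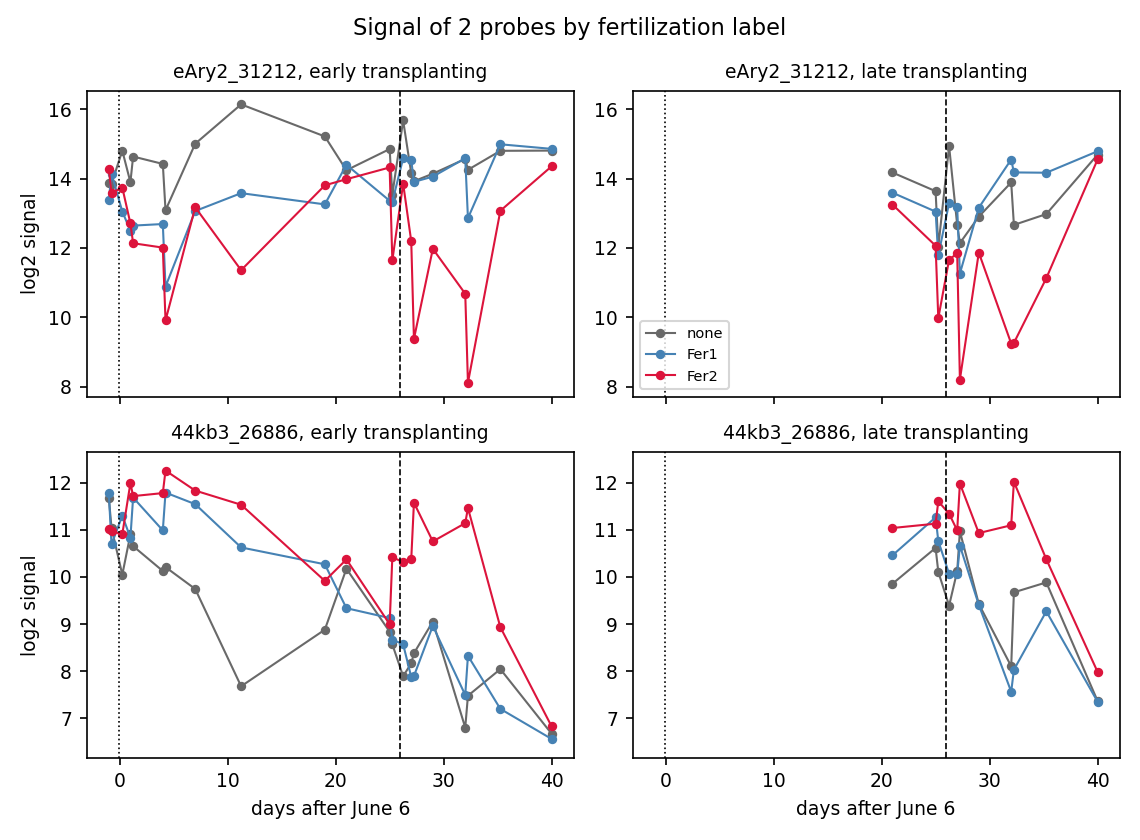
Lines give the log2 signal of probes eAry2_31212 and 44kb3_26886 against days after June 6, by label, in early and late plants; the dotted line marks the fertilization of June 6 and the dashed line that of July 2. After July 2 Fer2 is below Fer1 for eAry2_31212 and above it for 44kb3_26886 at 8 of 8 sampling times in both transplantings.

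The response to July 2 was traced by days as well. In early plants 8997 probes differed on days 0 to 1 (4422 higher, 4575 lower), 1495 on days 3 to 6 (773 and 722) and 38 on days 9 to 14 (17 and 21). In late plants the counts were 18, 1374 and 69. For eAry2_31212 the early changes were -2.52 ± 0.63, -3.59 ± 0.62 and -1.22 ± 0.77 log2 (adjusted p = 0.00774, 0.00102 and 0.909), and the late ones -2.01 ± 0.63, -3.82 ± 0.62 and -1.63 ± 0.77 (adjusted p = 0.454, 0.000342 and 0.558). For 44kb3_26886 the early changes were 2.64 ± 0.43, 2.85 ± 0.43 and 1.00 ± 0.52 log2 (adjusted p = 0.000145, 0.000206 and 0.824), and the late ones 1.17 ± 0.43, 3.02 ± 0.42 and 0.87 ± 0.52 (adjusted p = 0.606, 2.55e-05 and 0.714). With a slide block the first 2 early counts were 4952 and 844. Without July 3 at 10:40 or 16:20 the first was 3234 and 319. Without July 8 at 10:40 or 16:20 the middle one was 242 and 758. The last was 24 without July 3 at 10:40. In late plants the first was 53 with a slide block, 137 without July 2 and 34 without July 3 at 16:20. It was 11 without July 8 at 10:40, July 11 or July 16. The middle one was 162 and 615 without July 8 at 10:40 or 16:20. The last was 10 to 32 without any 1 time from July 2 to July 8. Days 9 to 14 hold 2 times, so leaving out July 11 or July 16 leaves 1 time there and decides nothing.

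Many probes moved in the same direction after both fertilizations, in samples and arrays that do not overlap, and others did not. Of the probes called after June 6 and after July 2 in early plants, 584 were higher in both (45.4 by chance) and 1580 lower in both (168.3 by chance), and 3 went opposite ways. The probes named as higher after June 6 were not called after July 2: eAry2_30365 had 0.50 ± 0.60 log2 in early and -0.10 ± 0.60 in late plants (adjusted p = 0.721 and 0.986), and 44kb3_35804 had 0.55 ± 0.55 and -0.05 ± 0.55 (adjusted p = 0.658 and 0.993). With late plants the shared counts were 178 (7.8 by chance) and 439 (30.5 by chance), with 0 opposite. Across probes r was 0.56 and 0.48, where probes are not independent replicates. In a test chosen after these calls were seen, the 7222 probes of June 6, signed by direction, had a mean score of 0.19 ± 0.09 log2 (SD, n = 8) in early and 0.15 ± 0.08 (n = 8) in late plants after July 2, positive at 8 of 8 times in both. The exact permutation p was 0.00781 in each, the smallest that 8 times allow (adjusted p = 0.0188 over 12 tests). In the other direction, the 5456 probes of July 2 in early plants scored 0.15 ± 0.11 log2 (SD, n = 11) after June 6, positive at 10 of 11 times (exact permutation p = 0.00195, adjusted p = 0.0117). With 1 mean score per date none of these passed the correction: p was 0.0313 in early and in late plants, the smallest that 6 dates allow, and 0.0156 over the 8 dates after June 6 (adjusted p = 0.0750 in each).

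**Figure D3:**
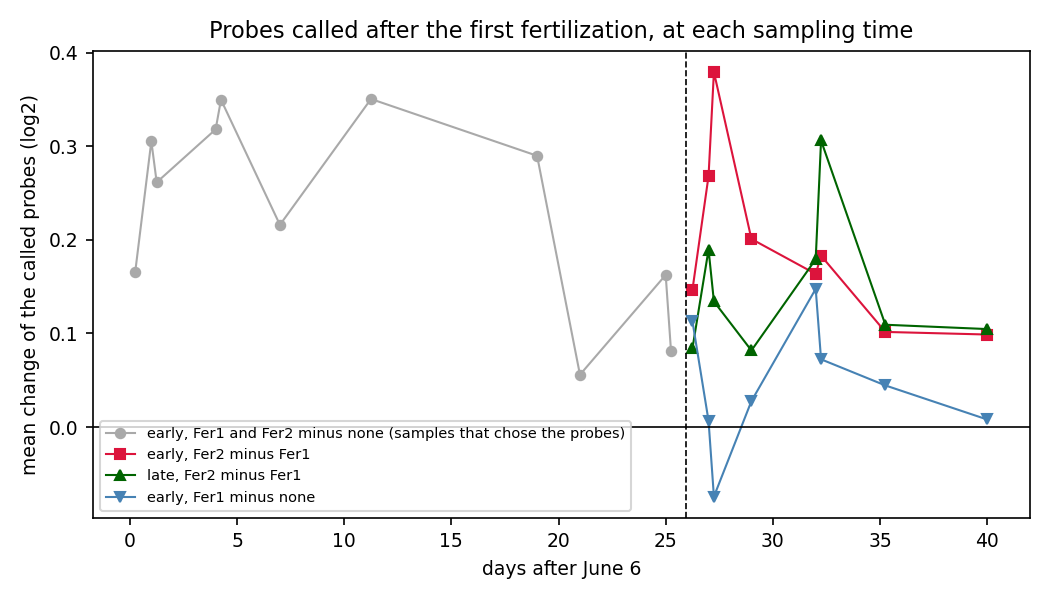
Points give the score (log2) of the 7222 probes called after June 6 at each sampling time, against days after June 6. The score averages the mean change of the higher probes and the mean change, sign turned, of the lower ones. Gray points are the samples that chose the probes. After July 2 (dashed line) Fer2 minus Fer1 lies above 0 at 8 of 8 times in early and in late plants, between 0.08 and 0.38, and Fer1 minus none at 7 of 8 times.

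Did the effect of June 6 last past July 2? Fer1 and unfertilized early plants, 26 to 40 days after June 6, differed in 3 probes by limma, which 7 of 100 splits of the labels reached, with 6365 at an unadjusted p under 0.05. Probe eAry2_33484 was higher by 0.33 ± 0.06 log2 (adjusted p = 0.0401), and eAry2_28777 (-0.36 ± 0.06, adjusted p = 0.0228) and eAry1_30575 (-0.36 ± 0.07, adjusted p = 0.0401) were lower, each at 8 of 8 times. For eAry2_31212 the change was -0.17 ± 0.39 log2 (adjusted p = 0.985). The 7222 probes of June 6 scored 0.04 ± 0.07 log2 (SD, n = 8), positive at 7 of 8 times, which did not pass the test (exact permutation p = 0.117, adjusted p = 0.156). Without July 3 at 16:20 they scored 0.06 ± 0.05 (n = 7), positive at 7 of 7 times (exact permutation p = 0.0156, the smallest that 7 times allow, adjusted p = 0.0313). That time held the only negative score, so leaving it out fixes this p, which decides nothing. With 1 mean score per date p was 0.125 (adjusted p = 0.214). The count was 0 without the array block, the dye term or the replicate block, with a slide block and with 1 mean per date (4636, 5089, 3848, 5817 and 5031 at an unadjusted p under 0.05), and 1 in the authors' table or with no filter. It was 0 without July 3 at 10:40, July 5, or July 8 at 10:40 or 16:20 (4987, 6634, 7149 and 5496 at an unadjusted p under 0.05), 1 without July 3 at 16:20 and 5 without July 11.

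How far do leaves differ between 10:40 and 16:20 on the same date? Of 101435 fitted probes 60064 differed over 6 dates, 31168 higher and 28896 lower in the afternoon, and 14536 at least 2-fold (7225 higher, 7311 lower). Probe eAry1_25080 (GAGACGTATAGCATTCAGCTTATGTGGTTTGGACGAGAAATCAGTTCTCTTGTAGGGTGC) rose from 7.84 ± 1.06 log2 (SD, n = 27) in the morning to 16.52 ± 0.56 (n = 27), a change of 8.50 ± 0.45 (SE, limma adjusted p = 1.96e-05), and 8.16 to 9.42 under the 13 alternatives. It was well above background in 25 of 27 morning samples, so the size of the change depends on how dim signal is treated. The overlapping 44kb3_18039 rose by 8.47 log2 (adjusted p = 2.02e-05). Probe 44kb3_960 (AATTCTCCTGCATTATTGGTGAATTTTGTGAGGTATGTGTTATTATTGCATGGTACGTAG) fell from 15.44 ± 0.83 to 8.62 ± 1.08 log2, by -6.67 ± 0.31 (adjusted p = 1.45e-05), and 44kb3_11643 fell by 6.67 on the log2 scale (adjusted p = 1.79e-05), each on 6 of 6 dates. Within the earlier scan day (4 dates) 22986 probes were higher and 20917 lower, and within the later (2 dates) 13996 and 12331.

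Transplanting date was compared in unfertilized plants sampled at the same 11 times, when late plants were 14 days younger from transplanting. Of 101270 fitted probes 17765 differed, 8192 higher and 9573 lower in late plants, and 204 at least 2-fold (66 higher, 138 lower). Probe 44kb3_14268 (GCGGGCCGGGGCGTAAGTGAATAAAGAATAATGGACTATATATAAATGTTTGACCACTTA) was higher in late plants at 11 of 11 times, at 13.83 ± 1.46 log2 (SD, n = 11) against 11.96 ± 1.83 (n = 11), a change of 1.93 ± 0.22 (SE, limma adjusted p = 0.00178). The overlapping eAry1_31338 rose by 1.91 log2 (adjusted p = 0.00185). The SE and adjusted p values of this comparison come from the model with the array correlation of -0.81. Under 20 alternatives, the one without the array block included, both probes kept their calls (limma adjusted p of at most 0.0117). Probe 44kb3_35804 (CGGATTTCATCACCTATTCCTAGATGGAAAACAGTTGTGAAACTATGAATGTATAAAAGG) was lower at 10 of 11 times, at 11.00 ± 1.87 against 13.33 ± 1.55 log2, by -2.33 ± 0.55 (adjusted p = 0.0160), and eAry1_14709 fell by 2.34 on the log2 scale (adjusted p = 0.0179). Probe eAry2_31212 fell by 1.11 on the log2 scale (adjusted p = 0.00350) and 44kb3_26886 rose by 1.43 log2 (adjusted p = 0.00350), the directions they had after fertilization. The count was 15843 without the array block, 44043 with all 3 labels, and 8778 with a slide block, where 44kb3_35804 (adjusted p = 0.0724) and eAry1_14709 (0.0751) lost their calls; it was 11282 and 10114 without July 3 at 10:40 and 16:20, and 10186 and 10591 without July 8 at 10:40 and 16:20. Without an array block and within the earlier scan day (3 times), limma called 0 probes, with 8897 at an unadjusted p under 0.05, and within the later (8 times) 6927 were higher and 7038 lower, with changes across probes at r of 0.71 and 0.98 with those of all 11 times.

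Leaves of unfertilized early plants changed from day 8 to day 49 after transplanting. Plant age, season and weather changed together over these days and cannot be told apart. Of 101440 probes 32442 had a slope, 18539 rising and 13903 falling, and 7770 changed at least 2-fold over the 41 days (4111 rising, 3659 falling). Probe 44kb3_35804, lower in late plants, had a slope of 0.17 ± 0.03 log2 per day (SE, n = 21, limma adjusted p = 0.000469), and the overlapping eAry2_30365 one of 0.17 (adjusted p = 0.000572). The course was not a steady rise: 44kb3_35804 stood at 11.83 and 12.81 log2 on June 5, at 6.24 to 7.01 on June 6 and 7, and at 13.85 to 15.07 from July 2 on. Probe eAry1_39069 (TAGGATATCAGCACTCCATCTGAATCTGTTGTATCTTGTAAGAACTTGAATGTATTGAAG) fell by 0.14 log2 per day (adjusted p = 1.69e-05), from a mean of 12.17 in the first 5 samples to 7.36 in the last 5. Probe 44kb3_35342 fell by 0.13 (adjusted p = 1.67e-05). Probe 44kb3_26886 fell by 0.09 log2 per day (adjusted p = 1.38e-05), and eAry2_31212 had a slope of 0.00 (adjusted p = 0.791). The scan day changed with the date: within the earlier one (13 samples) 3540 probes rose and 1826 fell, and within the later (8 samples) limma called 0 (7018 at an unadjusted p under 0.05), with slopes across probes at r of 0.83 and 0.40 with those of all samples. With the 10:40 samples alone the count was 2921, and 44kb3_35804 (adjusted p = 0.0524) and eAry2_30365 (0.0526) lost their calls.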

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

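The tests of June 7 at other points of the daily rhythm, of the July 11 array and of the array shared by early and late plants, and the counts over other splits, were chosen only after the results were seen.

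June 5 stood apart from the other dates in how far leaves changed between morning and afternoon. The root mean square of the change over all probes was 0.60 log2 on that date and 0.84 to 0.97 on the other 5 dates. It was 1 of 16 sets of values examined for a value far from the others, and chance sets apart about 1 in 20. No explanation was tested.

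In early plants, 2192 probes changed differently in the last and the first stage after June 6 (291 higher and 1901 lower in the last), in a test of the difference between stages. The call depends on settings: limma called 0 probes with the processed signal, without loess and with a slide block (13950, 14141 and 14062 at an unadjusted p under 0.05). It was 2 in the authors' table, 76 without June 7 and 724 without a dye term. Leaving out June 25, June 27 or July 1 at 10:40 gave 0 (12361, 11135 and 10709 at an unadjusted p under 0.05). Leaving out June 7 at 16:20 gave 25, and leaving out June 6, June 7 at 10:40 or July 1 at 16:20 gave 3574, 4752 and 4534.

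After July 2, 425 probes changed differently in the last and the first stage in early plants (117 higher and 308 lower in the last), while limma called 0 in late plants, with 7346 at an unadjusted p under 0.05. The early count was 30 with a slide block, 100 without a dye term and 163 with no filter on dim probes. It was 642, 673 and 883 without loess, with the stricter filter and without the array block. It was 2130 without July 2, 1 and 5 without July 3 at 10:40 and 16:20, and 1 without July 5. Leaving out July 11, its Fer2 array or July 16 leaves 1 time in the last stage and decides nothing.

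The Fer2 minus Fer1 difference of early plants was larger or smaller after July 2 than between June 6 and July 1 in 340 probes (100 higher, 240 lower). It was 0 without the replicate block (6515 at an unadjusted p under 0.05), 14 with 1 mean per date, 23 with a slide block, 67 at 2-fold or more, and 142 to 216 without a dye term, without the array block, with the processed signal, with no filter on dim probes and in the authors' table. Leaving out 1 time gave 133 (June 6), 221 (June 7 at 10:40), 139 (June 25), 111 and 622 (July 1 at 10:40 and 16:20), 53 and 59 (July 3), 142 (July 5), 139 and 131 (July 8) and 680 (July 16).

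Labels were reshuffled within sampling times to give other splits of the same samples, 100 per comparison with the real one included. Only the real split reached the real count for June 6 in early plants (7222, highest other split 4901), for July 2 in early plants (5456, highest other 43) and for July 2 in late plants (969, highest other 0). This argues against chance at the main settings, under which alone the splits were run. Labels of all periods were reshuffled together, so label effects of other periods can widen the spread and lower the counts of other splits. With 1 sampling time left out, the real counts went as low as 3662, 2394 and 215, the first of these below 4901. For these 3 counts chance is therefore not taken as excluded. In 2 of 100 splits the count beyond the earlier label difference was as large (340, highest other 1120). That share is under 0.05, 0.04 after adjustment over the 20 results tested by splits. However, the highest split called several times as many probes, and the count itself fell to 0, 14 and 23 under other settings. Chance is therefore not taken as excluded. For June 6 later on, 7 of 100 splits did as well (3, highest other 75), and chance cannot be excluded. For Fer2 against Fer1 with the same history and for late minus early, the real count was 0, which 100 of 100 splits must reach (highest others 11290 and 213), so the splits decide nothing there. Why 1 split gave 11290 calls was not tested. For the labels of late plants before July 2, 5 of 27 splits did as well (12, highest other 24), and chance cannot be excluded. For time of day 1 of 32 splits (60064, highest other 0) and for transplanting 1 of 100 splits (17765, highest other 462) reached the real count, the real one, which excludes chance taken singly; for time of day that share is the smallest that 32 splits allow, and it is 0.0568 after adjustment over the 20 results.

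For the stages after June 6, 13 of 100 splits reached the first-stage count (6088, highest other 17546), so chance cannot be excluded. For the middle stage it was 4 of 100 splits (5644, highest other 6562) and for last minus first 4 of 100 (2192, highest other 7627, several times the real count). These shares are under 0.05 taken singly, but after adjustment over the 20 results they are 0.0615. Other splits went beyond the real counts, so chance is not taken as excluded. The last stage had a real count of 0, which 100 of 100 splits must reach (highest other 1). After July 2 in early plants, 1 of 100 splits, the real one, reached the counts of the first stage (8997, highest other 5594), of the middle stage (1495, highest other 391) and of last minus first (425, highest other 59). In late plants the same held for the first stage (18, highest other 10) and the middle stage (1374, highest other 25). This argues against chance at the main settings, with the limits of the splits given above. With 1 time left out, the early counts went as low as 319, 242 and 1, each below its highest other split. The late ones went as low as 11 and 162, and the stricter filter on dim probes took the late first stage below 10. Chance is therefore not taken as excluded in these. Last minus first in late plants had a real count of 0, which 100 of 100 splits must reach (highest other 908), so this decides nothing.

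The 6088 calls of days 0 to 1 after June 6 depend on June 7 at 16:20, without which 171 were called, while the count was 6787 without June 6 and 7226 without June 7 at 10:40. Leaving out both June 7 times leaves 1 time in this stage (118 calls) and decides nothing. June 7 samples taken at other points of the daily rhythm are argued against as the main source of the label differences. The time of day accounted for at most 4.91% of their variance across probes. That test took the mean of Fer1 and Fer2, so opposite shifts of these labels would cancel in it, and a smaller shift stays open. On component 1, unfertilized, Fer1 and Fer2 leaves scored 107, 155 and 86 at 10:40 on June 7, and -106, -144 and -151 at 16:20. With 1 sample per label and time, a difference between plants or plots on that day stays open beside an early response to fertilizer, which was not tested apart from it.

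Both July 11 Fer2 samples, early and late, lay apart from the other labels of that time, and they share an array. A local defect of the array surface is argued against, since spots of the same sequence at different places gave r of at least 0.956 for the deviation. The response seen at the other sampling times is argued against as the whole of the deviation, with r of at most 0.0305 across probes (0.03 in early and -0.22 in late plants), against 0.11 to 0.53 and 0.07 to 0.44 at the other times, the lowest of which come close. It was not missing on July 11, since the probes of June 6 scored 0.10 and 0.11 log2, within the 0.10 to 0.38 and 0.08 to 0.31 of the other times. An effect of the whole array on both of its samples cannot be told apart from a state of the Fer2 plants on that date. The early and late deviations had r = 0.797 across probes, and neither sample was measured on another array.

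The changes after July 2 had r = 0.79 across probes between early and late plants, whose Fer2 samples share an array at 8 of 8 times. The 0 calls for late minus early do not show the changes to be alike. On days 0 to 1, 8997 probes were called in early and 18 in late plants, and no difference by stage was tested. Probes chosen on other arrays, those of June 6, had a positive score in late plants at 8 of 8 times, but also in early plants, so signal carried from the early to the late channel of an array would give the same. An effect of the shared array cannot be told apart from a response common to both transplantings, since no early and late Fer2 samples of 1 time lay on different arrays.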

How the results depend on the processing

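The alternatives without June 7 and without the July 11 array are tests chosen only after the results were seen; the others were fixed beforehand. Values are counts of called probes by limma, compared with those of the report; stages 1, 2 and 3 are days 0 to 1, 4 to 11 and 19 to 25 after June 6, or 0 to 1, 3 to 6 and 9 to 14 after July 2. Of 242 such counts under alternatives, 143 stayed within 1.5 times and 99 moved further. Stage 3 after July 2 holds 2 sampling times. Without July 11, its Fer2 array or July 16, the counts of that stage and of last minus first after July 2 rest on 1 time. Those counts decide nothing. Of 599 values of named probes, 524 kept their direction and their side of the threshold, 75 lost the threshold and 0 turned direction. The losses fell mostly on eAry2_33484 (17 of 18 alternatives), eAry1_30575 (13 of 18), eAry2_28777 (9 of 18) and eAry2_07376 (8 of 11). Signal near background weighs on the counts on June 5 and in late plants before July 2: they were 89 and 12 with the filter on dim probes, 510 and 151 without it, and 26 and 9 with the stricter one. The estimated gene list correlation and the mean over probes of a gene were not run, since no probe has a gene name. Leaving out the replicate block puts variation between sampling times into the spread, so fewer calls there do not by themselves show smaller changes. Other than by construction (that, a 2-fold threshold, fewer samples or probes), the cause was not tested.

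At 2-fold or more, the counts were 39 (June 6 early), 24 (before any), 2 (late before July 2), 144 (July 2 early), 66 (July 2 late), 67 (beyond the earlier difference), 0 (June 6 later on, 30 at unadjusted p under 0.05), 81 (June 6 early stage 1), 111 (June 6 early stage 2), 67 (June 6 early last minus first), 377 (July 2 early stage 1), 289 (July 2 early stage 2), 19 (July 2 early stage 3), 158 (July 2 early last minus first), 11 (July 2 late stage 1), 227 (July 2 late stage 2), 39 (July 2 late stage 3), 14536 (time of day), 204 (transplanting) and 7770 (days). From the processed signal, they were 22 (before any), 0 (late before July 2, 3195 at unadjusted p under 0.05), 163 (beyond the earlier difference), 0 (June 6 early last minus first, 13950 at unadjusted p under 0.05), 23 (July 2 early stage 3) and 1 (July 2 late stage 3). With no loess, they were 54 (before any), 20 (late before July 2), 0 (June 6 early last minus first, 14141 at unadjusted p under 0.05), 642 (July 2 early last minus first) and 1 (July 2 late last minus first). The authors' value table gave 18 (before any), 0 (late before July 2, 2690 at unadjusted p under 0.05), 216 (beyond the earlier difference), 1 (June 6 later on), 3737 (June 6 early stage 2), 2 (June 6 early last minus first) and 2 (July 2 late stage 3). Without a filter on dim probes, they were 510 (before any), 151 (late before July 2), 213 (beyond the earlier difference), 1 (June 6 later on), 3 (June 6 early stage 3), 114 (July 2 early stage 3), 163 (July 2 early last minus first), 240 (July 2 late stage 3) and 4 (July 2 late last minus first). Among probes well above background in at least 48 samples, they were 26 (before any), 673 (July 2 early last minus first), 5 (July 2 late stage 1) and 5 (July 2 late stage 3). Without the array block, they were 20 (late before July 2), 154 (beyond the earlier difference), 0 (June 6 later on, 4636 at unadjusted p under 0.05), 883 (July 2 early last minus first), 35 (July 2 late stage 3) and 1 (July 2 late last minus first). Without a dye term, they were 4271 (June 6 early), 142 (beyond the earlier difference), 0 (June 6 later on, 5089 at unadjusted p under 0.05), 3232 (June 6 early stage 1), 2858 (June 6 early stage 2), 724 (June 6 early last minus first), 23 (July 2 early stage 3), 100 (July 2 early last minus first), 11 (July 2 late stage 1), 32 (July 2 late stage 3) and 2 (July 2 late last minus first). A slide block gave 0 (late before July 2, 2666 at unadjusted p under 0.05), 23 (beyond the earlier difference), 0 (June 6 later on, 5817 at unadjusted p under 0.05), 2653 (June 6 early stage 2), 0 (June 6 early last minus first, 14062 at unadjusted p under 0.05), 4952 (July 2 early stage 1), 844 (July 2 early stage 2), 30 (July 2 early last minus first), 53 (July 2 late stage 1), 37 (July 2 late last minus first) and 8778 (transplanting). Without the replicate block of sampling times, they were 3087 (June 6 early), 2 (late before July 2), 184 (July 2 early), 0 (July 2 late, 2380 at unadjusted p under 0.05), 0 (beyond the earlier difference, 6515 at unadjusted p under 0.05) and 0 (June 6 later on, 3848 at unadjusted p under 0.05). Taking 1 mean per date gave 3397 (June 6 early), 56 (late before July 2), 2524 (July 2 early), 195 (July 2 late), 14 (beyond the earlier difference) and 0 (June 6 later on, 5031 at unadjusted p under 0.05). All 3 labels (33 pairs) gave 44043 (transplanting). The 10:40 samples alone gave 2921 (days). Without June 7, chosen after seeing the data, the counts were 118 (June 6 early stage 1) and 76 (June 6 early last minus first). Without the array of both July 11 Fer2 samples, also chosen after seeing the data, they were 8549 (July 2 early), 71 (July 2 early stage 3), 35 (July 2 early last minus first) and 48 (July 2 late last minus first). With each sampling time left out in turn, the counts ranged from 185 to 480 (before any), 3662 to 8364 (June 6 early), 0 to 16 (same history), 53 to 680 (beyond the earlier difference), 171 to 7226 (June 6 early stage 1), 2084 to 8457 (June 6 early stage 2), 0 to 2 (June 6 early stage 3), 0 to 4752 (June 6 early last minus first), 3 to 84 (late before July 2), 2394 to 6969 (July 2 early), 215 to 1096 (July 2 late), 0 to 0 (late minus early), 0 to 5 (June 6 later on), 319 to 9326 (July 2 early stage 1), 242 to 1651 (July 2 early stage 2), 24 to 1483 (July 2 early stage 3), 1 to 3459 (July 2 early last minus first), 11 to 137 (July 2 late stage 1), 162 to 1595 (July 2 late stage 2), 10 to 5987 (July 2 late stage 3), 0 to 4500 (July 2 late last minus first), 50795 to 62107 (time of day), 10114 to 19621 (transplanting) and 27457 to 35980 (days).

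Leaving out June 6 at 16:20 gave 3574 (June 6 early last minus first). Without June 7 at 10:40 the counts were 4752 (June 6 early last minus first). Omitting June 7 at 16:20 gave 171 (June 6 early stage 1) and 25 (June 6 early last minus first). Leaving out June 10 at 10:40 gave 3603 (June 6 early stage 2). Without June 10 at 16:20 the counts were 2084 (June 6 early stage 2). Omitting June 17 at 16:20 gave 2156 (June 6 early stage 2). Leaving out June 25 at 10:40 gave 2 (June 6 early stage 3) and 0 (June 6 early last minus first, 12361 at unadjusted p under 0.05). Without June 27 at 10:40 the counts were 0 (June 6 early last minus first, 11135 at unadjusted p under 0.05). Omitting July 1 at 10:40 gave 2 (June 6 early stage 3) and 0 (June 6 early last minus first, 10709 at unadjusted p under 0.05). Leaving out July 1 at 16:20 gave 4534 (June 6 early last minus first). Without July 2 at 16:20 the counts were 2130 (July 2 early last minus first), 137 (July 2 late stage 1), 18 (July 2 late stage 3) and 6 (July 2 late last minus first). Omitting July 3 at 10:40 gave 3234 (July 2 early stage 1), 24 (July 2 early stage 3), 1 (July 2 early last minus first) and 21 (July 2 late stage 3). Leaving out July 3 at 16:20 gave 319 (July 2 early stage 1), 5 (July 2 early last minus first), 34 (July 2 late stage 1), 13 (July 2 late stage 3) and 6 (July 2 late last minus first). Without July 5 at 10:40 the counts were 1 (July 2 early last minus first), 32 (July 2 late stage 3) and 2 (July 2 late last minus first). Omitting July 8 at 10:40 gave 242 (July 2 early stage 2), 11 (July 2 late stage 1), 162 (July 2 late stage 2) and 31 (July 2 late stage 3). Leaving out July 8 at 16:20 gave 758 (July 2 early stage 2), 615 (July 2 late stage 2), 10 (July 2 late stage 3) and 1 (July 2 late last minus first). Without July 11 at 16:20 the counts were 29 (July 2 early last minus first), 11 (July 2 late stage 1) and 36 (July 2 late last minus first). Omitting July 16 at 10:40 gave 1483 (July 2 early stage 3), 3459 (July 2 early last minus first), 11 (July 2 late stage 1), 5987 (July 2 late stage 3) and 4500 (July 2 late last minus first).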

Other observations

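The exact permutation tests below, with and without single sampling times and by date, were chosen only after the results were seen.

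On July 1 at 16:20, the day before the second fertilization, Fer2 leaves differed from Fer1 leaves in the direction seen after it. In early plants eAry2_31212 stood at 11.64 log2 in Fer2, 13.33 in Fer1 and 13.54 in unfertilized leaves, while at 10:40 on that day it had stood at 14.32, 13.36 and 14.85. Probe 44kb3_26886 stood at 10.42, 8.67 and 8.57 log2, after 9.00, 9.13 and 8.84 at 10:40. In late plants eAry2_31212 stood at 9.97 log2 in Fer2, 11.79 in Fer1 and 12.02 in unfertilized leaves, and was lower in Fer2 at 10:40 as well (12.07, 13.05 and 13.64). Such a gap was not new: on June 17 the same probe stood at 11.36 log2 in early Fer2, 13.58 in Fer1 and 16.14 in unfertilized leaves. The 5456 probes of July 2 in early plants, signed by direction, scored 0.25 log2 for Fer2 minus Fer1 at that time, the highest of the 11 times before July 2 (-0.04 to 0.13 at the others). Over the 11 times the score was 0.05 ± 0.08 log2 (SD, n = 11), positive at 8 (exact permutation p = 0.0400, adjusted p = 0.0801), and did not pass the correction. With 1 mean score per date p was 0.0703 (adjusted p = 0.141). Without July 1 at 16:20 the exact permutation p was 0.0801 (adjusted p = 0.120). That these samples precede the second fertilization rests on the dates in the labels. Without them limma called 0 probes between Fer2 and Fer1 before July 2 (6480 at an unadjusted p under 0.05), and 622 in place of 340 for the difference after July 2 beyond the earlier one. No explanation was tested.

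In late plants before July 2, the probes called after June 6 in early plants scored 0.07 ± 0.03 log2 (SD, n = 3) for Fer1 and Fer2 against none. The score was positive at 3 of 3 times, with an exact permutation p of 0.25, the smallest that 3 times allow. At these times each late sample shares an array with an early sample that helped choose the probes, so the score is not independent of that choice. After July 2, Fer1 against none in late plants scored -0.01 ± 0.09 log2 (SD, n = 8), positive at 4 of 8 times (exact permutation p = 0.805).

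Spots that carry the same sequence at different places of the array gave like changes. Over 2509 pairs of such probes r was 0.929 after June 6, 0.946 and 0.894 after July 2 in early and late plants, and 0.998 for the time of day, across probes.

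A response shared by both fertilizations may account for the common probes. Probes called after June 6 moved the same way after July 2 in other samples and on other arrays, at 8 of 8 times in early and in late plants, with an exact permutation p of 0.00781 in each. With 1 mean score per date p was 0.0313 in each, the smallest that 6 dates allow, and did not pass the correction (adjusted p = 0.0750). A lasting difference between plots that carry the labels is not excluded by that test, since the labels do not name plots.

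Fertilized leaves could resemble leaves of younger plants. Days after transplanting stand for age here, but age, season, weather and scan day change together in them. All scored samples are of the later scan day, within which limma called 0 slopes. The samples that gave the slope include the 8 scored times. On July 8, 11 and 16 they share an array with early Fer1, so the scores may not be independent of the choice of probes. The 32442 probes with a slope on days after transplanting, signed so that falling ones count in reverse, scored -0.10 ± 0.12 log2 (SD, n = 8) for Fer2 minus Fer1 in early plants, negative at 6 of 8 times (exact permutation p = 0.0469, adjusted p = 0.0804). In late plants they scored -0.06 ± 0.13 (n = 8), negative at 7 of 8 times, with p = 0.273 by the same exact test. The positive score is that of July 11 (0.23), whose Fer2 array lies apart from the others. Without July 11 the late score was -0.10 ± 0.07 (n = 7), negative at 7 of 7 times (exact permutation p = 0.0156, the smallest that 7 times allow, adjusted p = 0.0313), and the early one -0.13 ± 0.10 (p = 0.0313, adjusted p = 0.0625). Leaving out the only positive late score fixes the late p, which decides nothing. With 1 other time left out, p was 0.0469 to 0.0938 in early and 0.328 to 0.547 in late plants. With 1 mean score per date p was 0.188 and 0.594 (adjusted p = 0.250 and 0.648). The hypothesis asked for both transplantings and stays open, since the late result turns on 1 array.

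Fertilized leaves could also resemble leaves of later transplanted plants. The unfertilized samples that chose these probes include the 8 scored times. On July 8, 11 and 16 they share an array with the Fer1 sample of their transplanting, so these scores may not be independent of the choice either. The 17765 probes that differed between late and early unfertilized plants, signed so that those lower in late plants count in reverse, scored 0.15 ± 0.07 log2 (SD, n = 8) for Fer2 minus Fer1 in early plants, positive at 8 of 8 times (exact permutation p = 0.00781, adjusted p = 0.0188). In late plants the score was 0.11 ± 0.15 (n = 8), positive at 7 of 8 times, with p = 0.0625 by the same exact test. The negative score is again that of July 11 (-0.13). Without it the late score was 0.14 ± 0.12 (n = 7), positive at 7 of 7 times (exact permutation p = 0.0156, adjusted p = 0.0313), and with 1 other time left out p was 0.0938 to 0.125. Leaving out the only negative late score fixes the p of 0.0156, which decides nothing. With 1 mean score per date p was 0.0313 in early and 0.188 in late plants (adjusted p = 0.0750 and 0.250). Over all 8 times late plants miss what the hypothesis asked for, and it stays open for the same reason.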
